A study of Mus musculus with 41 samples.

How the data were processed

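Copy number was measured in tumour DNA from 41 high-grade astrocytomas of 35 mice by array comparative genomic hybridisation, in which tumour DNA and reference DNA carry different dyes and compete for the same probes. Per the labels, tumours were flash-frozen, DNA was extracted with a column kit, tumour DNA was labelled with Cy5, and reference DNA pooled from the brains of 10 littermates was labelled with Cy3. The labels describe the pool in 2 wordings, 1 of them on a single array (TR tumour 1). Every array had the same dye orientation, so a dye effect of a probe does not cancel. Per the labels, 8 tumours of 7 mice carried the genotype TR, 25 tumours of 21 mice TRPhet and 8 tumours of 7 mice TRPnull. The letters of the genotypes, the brain locations (BS, Ctx, Di, OFB) and the diagnoses (A3, GBM, GC-GBM) are used as the labels give them.

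Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1, and probe positions are on genome build mm8 (NCBI36). The deposited intensity values are processed signals per channel. They are background-subtracted, detrended over the slide and scaled between dyes within the array by a linear factor, per the file headers, with no curve fitted over intensity. The deposited series table holds log2 values made by the authors, 1 column per array, whose normalisation is not given in the sources used here. Set against the scanner values of the same array, 40 of its columns had slopes of 0.667 to 0.934 and correlations of 0.849 to 0.992, so their scale is log2 and their direction is tumour over reference. The column of TRPhet tumour 22 had a slope of 0.291 and a correlation of 0.431, and did not match its own array best. Column medians lay between -0.022 and 0.018, and between 1.50% and 10.3% of the cells per column were empty. What kind of centring or smoothing the authors applied stays unknown, and the table served as an alternative only.

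The log2 ratio of processed Cy5 over processed Cy3 signal was computed per spot. Control spots and spots marked as non-uniform in either channel (4 to 242 per array) were left out, which left at most 235988 spots at 233212 positions. Spots at one position were averaged, and each array was centred on the median of its 220668 autosomal positions, with no loess or quantile step. The median spacing of autosomal positions was 7.83 kb. Before the data were examined, the groups, the tests, the alternatives, 10 gene lists and the rule for naming genes were fixed. That plan held no test of the mean level of chromosome 6 or of the gained and lost shares. Where p of those tests are adjusted, it is over pairs of groups only. X and Y were left out of all totals, because the sex of the mice is not in the labels.

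Each autosome was divided into segments by penalised least squares (exact dynamic programming, penalty 4 times the noise variance times the natural logarithm of the number of probes per break), with single values limited to 3 SD around a running median of 11 probes and a smallest segment of 3 probes. A segment counted as gained or lost with at least 10 probes and a mean log2 ratio of at least 0.2 in size, and as large from 5 Mb. A chromosome counted as gained or lost where such segments held at least 70% of its probes. The altered share is the percentage of the probed autosomal span (2403 Mb) in gained or lost segments.

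Arrays give no read depth, so their number limits the precision. The noise per array (spread of differences between neighbouring probes) ranged from 0.145 to 0.576 with a median of 0.235, and 10 arrays lay above 1.5 times the median. Between 97.8% and 99.97% of the probes per array were well above background in both channels. The 8 scan days were treated as batches (scan batch 1 to 8, with 10, 10, 2, 3, 5, 4, 5 and 2 arrays). Each slide held 1 array, so no slide effect could be fitted. The correlation between arrays over all autosomal positions had a median of 0.39 over 820 pairs. In 2 pairs it was under -0.3, with -0.32 as the lowest, and both held TRPnull tumour 1. The dyes are stated in the labels and were kept as given.

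The mouse was the replicate for genotype and diagnosis, with the tumours of 1 mouse averaged. The tumour was the unit for brain region, since the 6 mice with 2 tumours had them in different regions. Differences of means were tested by two-sided permutation, exact up to 2000000 splits and otherwise with 100000 resamples. Region effects were tested by permuting the between-region sum of squares, reported as the percentage of the variance. Recurrence of whole chromosome events was tested by reassigning each mouse's events among the 19 autosomes (38 tests, one-sided), and frequencies among genotypes with the exact Freeman-Halton test. Likeness of 2 tumours of 1 mouse was tested exactly over 720 matchings. Benjamini-Hochberg adjustment was used over pairs of genotypes or regions, chromosome events and genes, whereas p of region effects, of diagnosis differences and of interactions are unadjusted. Intervals of shares are exact Clopper-Pearson intervals at 95%.

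Gene values are means of the log2 ratios of at least 2 positions carrying one gene name in the array files (16308 genes). Of 24704 gene names on 1 autosome, 12376 equal a current symbol of the GRCm38.p6 annotation, 3085 were matched through an older name and 9243 kept the name of the array. That annotation was used for names only. Genes were tested with limma (lmFit, duplicateCorrelation with the mouse as block, eBayes), with the correlation within mice estimated at 0.163, 0.154 and 0.233 for the genotype, region and diagnosis models. Gain or loss against the reference was tested with limma's treat at a bound of 0.1, on the mean of the 3 genotypes weighted equally. As a test against 0, it leaves out the spread of normal brain samples. Neighbouring genes share segments, so a count of genes is not a count of events.

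The gene lists cover receptor tyrosine kinases, the RAS and MAPK pathway, the PI3K pathway, RB and the cell cycle, p53 and DNA damage, MYC and other transcription factors, glioma suppressors and chromatin regulators, neural lineage, segments known to vary between mouse strains, and antigen receptor loci as markers of lymphocytes. Of 205 listed names, some of them a second name of the same gene, 153 are on the array. No antigen receptor gene is named there, so that list gave no result. Results of some genes, planned ones among them, are not reported here. Named genes are the 12 list genes gained and the 12 lost in the most tumours, list genes in segments of at least 1 in size, and per contrast the 10 list genes with the smallest adjusted p under 0.05 or, where none passed, the 3 with the smallest p as values. Named regions are the 10 narrowest altered in the same direction in at least 4 mice by segments under 5 Mb. Other genes and regions named in the text were chosen after their values were seen.

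The arrays labelled TRPhet tumour 4 and TRPnull tumour 4 differed by less than the spread between duplicate spots. They belong to different groups and could not be averaged into 1 sample, so the main result of each comparison, the recurrence of chromosome events and the gene tests were also computed without both. Alternatives covered the size threshold, the penalty, probes per segment, centring on the densest value (-0.22 to 0.22 from the median, over 0.1 in size on 5 arrays), normexp background correction (offset 50), the authors' values, spot filters, subtraction of each probe's median, noisy arrays, units, batch and region strata, limma models and leaving out each mouse. Added after the data were examined were runs without both alike arrays, without TRPhet tumour 22, and with only the tumours whose X lay above and Y below the reference.

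On simulated data with known changes in the TRPnull against TR comparison (16308 genes), limma recovered 15.5%, 88.5% and 100% of 200 genes shifted by 0.2, 0.4 and 0.8, and called 0 unchanged genes. In the real data Ezh2 differed by -0.49 ± 0.13 (SE) in that comparison and was not called (limma adjusted p = 0.101). The recovered shares therefore do not rule out real differences near 0.4 in genes with such a spread. Segments of 1000 probes with a shift of 0.3 were found in 19 of 19 cases on a quiet, a median and a noisy array. Segments of 100 probes with that shift were found in 19, 17 and 2 of 19. The permutation test gave a p under 0.05 in 9 of 200 random groupings (4.5%). Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, R 4.3.3 and limma 3.58.1.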

Results

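DNA copy number was measured along the genome in 41 high-grade astrocytomas, malignant glial brain tumours, from 35 engineered mice. The tumours fell into 3 genotypes, with 8 TR tumours from 7 mice, 25 TRPhet tumours from 21 mice and 8 TRPnull tumours from 7 mice. By brain location, 16 tumours were labelled BS, 7 Ctx, 8 Di and 10 OFB, and by diagnosis 12 were labelled A3, 28 GBM and 1 GC-GBM. Each array compared the tumour with pooled normal brain DNA, so a log2 ratio above 0 stands for more copies in the tumour than in the pool. The noise of neighbouring probes ranged from 0.145 to 0.576 (median 0.235). The median Cy5 signal ranged from 212 to 470 and the median Cy3 signal from 121 to 275. The design text asks how often these tumours carry gains and losses and whether the frequency varies by genotype and brain region.

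Whole chromosome gains dominated the copy number changes, and chromosome 6 was gained in 24 of the 41 tumours. The gain was present in 21 of 35 mice (60%), with a mean log2 ratio over the chromosome of 0.49 in the tumours that carried it (range 0.27 to 0.84). At a size threshold of 0.5, and with each probe's median subtracted, 9 mice had it. Gain of chromosome 1 came next, in 7 tumours of 7 mice (20%) with a mean of 0.32 (0.23 to 0.44). Chromosome 15 was gained in 3 tumours (mean 0.31), TR tumour 2 and TRPhet tumours 23 and 24. Chromosomes 3 (0.22) and 11 (0.23) were gained in TRPhet tumour 24 alone. Whole chromosome losses were seen in TR tumour 8, which had lost chromosome 7 (-0.39) and chromosome 11 (-0.39), and in TRPhet tumour 22, which had lost chromosome 19 (-0.52), in a segment from 10439610 to 61316020 with a mean of -0.66 (build mm8). Against random placement of each mouse's events among the autosomes, the gain of chromosome 6 was more frequent (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted 0.00038), as was the gain of chromosome 1 (adjusted permutation p = 0.0154). No other of the 38 chromosome events passed this test. The call for chromosome 1 ended at size thresholds of 0.3 and 0.5, where 2 mice and 0 mice had the gain, and with centring on the densest value, where 8 mice had it.

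At least 1 large segment, of 5 Mb or more, was called in 27 of 41 tumours (65.9%, 95% interval 49.4% to 79.9%). Large gains were present in 26 tumours, large losses in 6 and both in 5, while a segment of any length was called in 40. The count was 8 of 8 in TR, 16 of 25 in TRPhet and 3 of 8 in TRPnull. By region it was 15 of 16 in BS, 2 of 7 in Ctx, 5 of 8 in Di and 5 of 10 in OFB. Large losses short of a whole chromosome lay on chromosome 4 in TRPhet tumour 13 (49078469 to 104582889, mean -0.20), on chromosomes 11 and 14 in TRPhet tumour 5, on chromosome 8 in TRPhet tumour 6, and on chromosomes 1, 8, 14 and 15 in TRPhet tumour 7. Means of these losses, from -0.26 to -0.20, lay near the threshold of 0.2. The chromosome 8 losses of TRPhet tumour 6 (99345632 to 106880354) and TRPhet tumour 7 (99331055 to 106781123) nearly coincide, and why was not tested. Partial gains lay on chromosomes 2, 5 and 8 in TR tumour 8, the last from 3111085 to 16975793 with a mean of 0.52, and on chromosome 5 in TRPhet tumour 22 (123261594 to 152002764, mean 0.50). In TRPnull tumour 2 part of chromosome 6 was called gained (112254407 to 129603340, mean 0.20). This call too lies near the threshold, and the mean over its whole chromosome 6 was 0.135. The design text gives 93% of tumours with gains and losses and no criteria. The count fell to 13 tumours at a size threshold of 0.5 and rose to 34 with segments of at least 1 Mb. Segments under 5 Mb include regions that recur over mice and may be inherited variants. Both the 34 tumours and the 40 with a segment of any length may therefore count such variants.

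**Figure D1:**
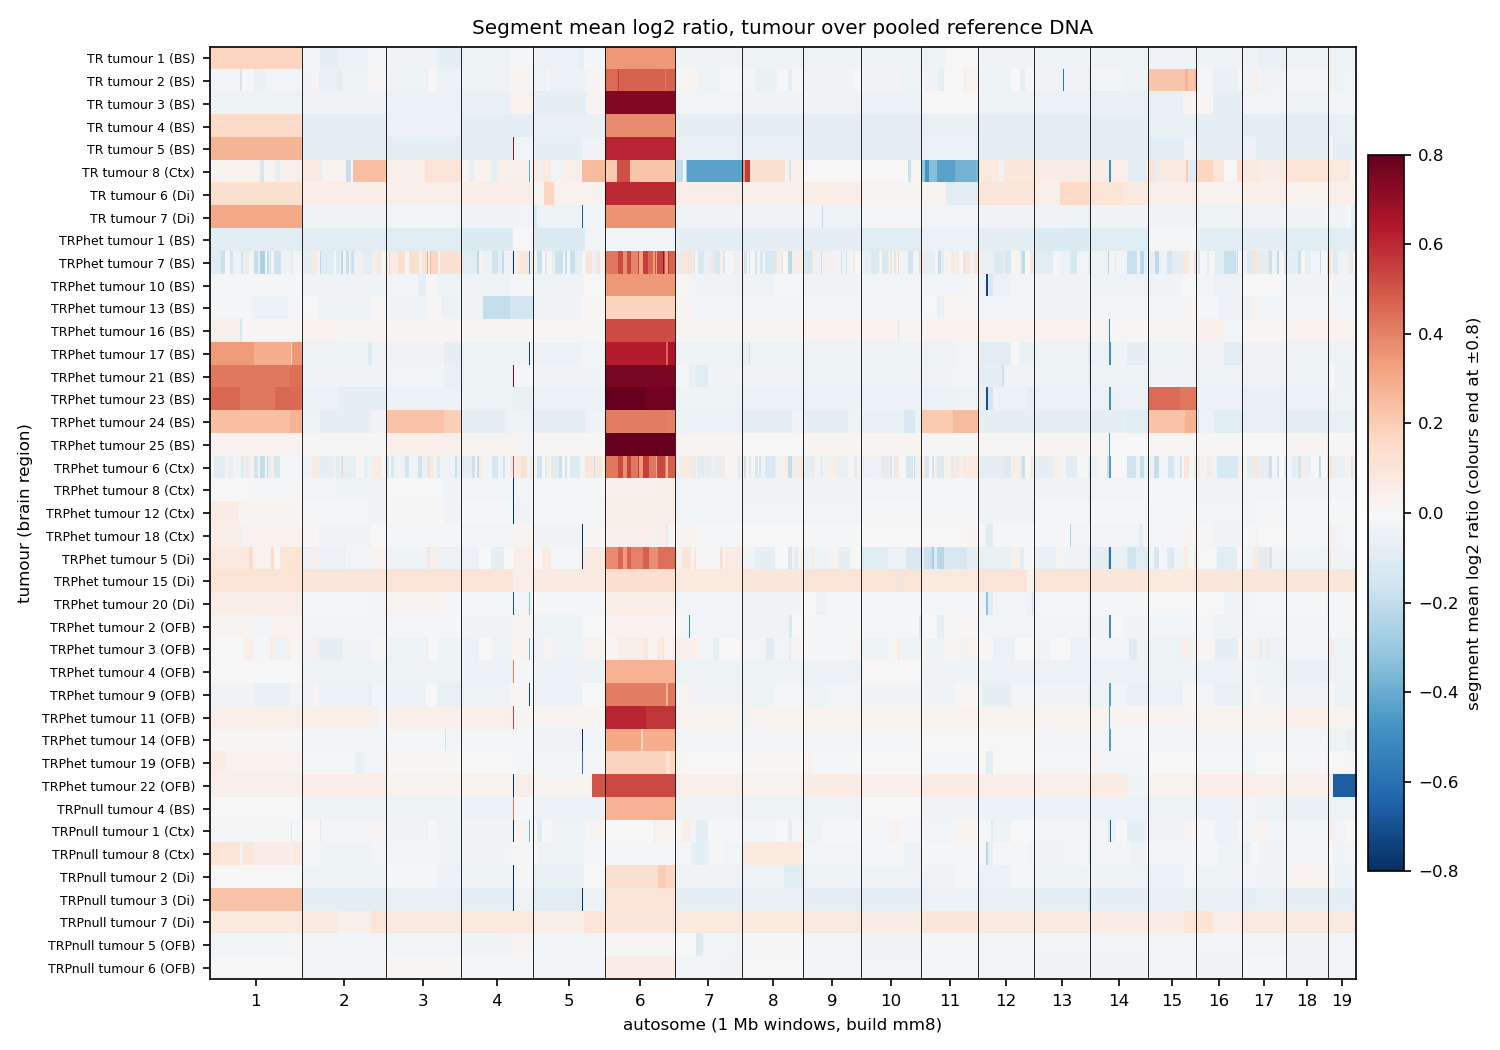
Segment mean log2 ratio (colour, ending at 0.8 in size) in 1 Mb windows along the 19 autosomes (horizontal axis) for each tumour (vertical axis), ordered by genotype and brain region. Chromosome 6 stands out as gained in 24 tumours and chromosome 1 in 7.

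Among the listed cancer genes, those on chromosome 6 were gained most often. The kinase gene Braf, the cyclin gene Ccnd2, the transcription factor gene Foxm1, the histone methyltransferase gene Ezh2 and the receptor gene Met were each called gained in 24 or 25 tumours and lost in none. Limma's treat, at a bound of 0.1, tested the mean of the 3 genotypes, each weighted equally, in a fit of all 41 tumours. By this test Foxm1 rose by 0.50 ± 0.05 (SE, adjusted p = 8.13e-08) and Ccnd2 by 0.42 ± 0.04 (adjusted p = 2.37e-07). Braf rose by 0.41 ± 0.05 (adjusted p = 9.58e-07), Ezh2 by 0.40 ± 0.05 (adjusted p = 2.33e-06) and Met by 0.28 ± 0.04 (adjusted p = 0.000711). The mean segment values of these genes lay between 0.31 (Met) and 0.33 (Braf), so their own values do not rank degrees of gain. All of them lie on chromosome 6, with Met at 17442331 to 17512182, Braf at 39543097 to 39640931, Ezh2 at 47459839 to 47521906 and Ccnd2 at 127094255 to 127113965.

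By list, 3 of the 12 tested RAS and MAPK genes, Braf among them, rose and none fell, and 1 of 13 RB and cell cycle genes (Ccnd2) rose. Of 18 receptor tyrosine kinases, Met rose and Kdr, the VEGF receptor gene, fell (-0.15). Of 15 p53 and DNA damage genes, the p53 inhibitor genes Mdm2 (0.28 ± 0.03, above 0 in 40 of 41 tumours) and Mdm4 (0.21) rose and the checkpoint kinase gene Chek1 (-0.16) fell. Of 7 MYC and transcription factor genes, Foxm1 rose and Gli1, the effector of hedgehog signalling, fell (-0.30 ± 0.04). Of 19 glioma suppressor and chromatin genes, Ezh2 and Lzts1 (0.21) rose. None of the 18 PI3K pathway entries (Mtor is listed under a pair of names) and none of the 6 neural lineage genes passed limma's treat, with smallest unadjusted p of 0.0119 (Pik3cd) and 0.00880 (Nes). Adjusted over the list alone, the counts were the same in each of these lists. Mdm2, Gli1, Mdm4, Kdr, Chek1 and Lzts1 lie outside chromosome 6. Mdm2, Gli1, Kdr, Chek1 and Lzts1 were in no called segment (mean segment values from -0.03 to 0.00), and Mdm4, on chromosome 1, was called gained in 7 tumours. For the genes in no called segment, a rise or fall describes their own probes only, and no copy number change is shown. Kdr, Chek1 and Mdm4 were chosen after their values were seen.

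Over all genes, treat called 2799 of 16308, of which 1912 were higher and 887 lower than the reference (68.3% higher). On chromosome 6, 755 of 923 genes were called higher (81.8%), and on chromosome 1 224 of 1121 (20%). Each of the other autosomes had calls both ways, from 4.07% (chromosome 18) to 8.46% (chromosome 15) of its genes higher. Between 1.96% (chromosome 15) and 8.13% (chromosome 18) were lower. With centring on the densest value 2134 of 2642 called genes were higher (80.8%). In 1 Mb windows, where single probes weigh less, 153 of 2408 passed and 144 of them were gained windows of chromosome 6. Among the named genes outside strain-variable segments, losses were single: the tumour suppressor genes Cdkn2a and Ptprd on chromosome 4 and Lrp1b on chromosome 2 were each called lost in 1 tumour, as was Igf1r on chromosome 7. So were the strain-variable genes Trim30 on chromosome 7 and Fgfbp3 on chromosome 19. Cdkn2a and Ptprd lie in the same lost segment of TRPhet tumour 13, with a mean of -0.20, so theirs is a single event. That value and the -0.21 of Lrp1b lie near the threshold of 0.2. Since every array carried tumour DNA in Cy5, the test against the reference does not separate a shared copy number change from a probe's dye effect, and no gene passed after each probe's median was subtracted (7 at an unadjusted p under 0.05), a step that by construction removes a change present in most arrays.

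TR tumours carried the most copy number change and TRPnull tumours the least. The altered share of the autosomes averaged 11.3% ± 6.0 (SD, n = 7 mice) in TR, 6.60% ± 7.18 (n = 21) in TRPhet and 2.28% ± 3.49 (n = 7) in TRPnull. TRPnull lay below TR (difference -9.04 percentage points, exact permutation p = 0.00583, adjusted 0.0175). Over the alternatives the difference ranged from -16.2 to -1.94 and no longer passed in 5 of them. The differences of -4.72 between TRPhet and TR and of -4.33 between TRPnull and TRPhet were within the spread between mice (exact permutation tests, adjusted p = 0.134 for both). Across the alternatives these 2 ranged from -7.15 to 2.07 and from -14.3 to -2.03, so the place of TRPhet depends on the processing. The gained share followed the same order, with TRPnull minus TR at -7.69 (exact permutation test, adjusted p = 0.0175), whereas the lost share did not differ between any genotypes (exact permutation tests, adjusted p from 0.383 to 0.965).

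Of whole chromosomes, only 1 and 6 were compared by genotype, and chromosome 6 showed a difference. Its gain was present in 7 of 7 TR mice, 13 of 21 TRPhet mice and 1 of 7 TRPnull mice (exact Freeman-Halton p = 0.0037, adjusted 0.0074), while gain of chromosome 1 was present in 2 of 7, 4 of 21 and 1 of 7 (adjusted exact p = 0.852). In 4 tumours, TRPnull tumour 2 and TRPhet tumours 13, 15 and 19, chromosome 6 averaged between 0.1 and 0.2 without a call of the whole gain. The counts of the gain therefore depend on the threshold. The mean log2 ratio of chromosome 6 was 0.44 ± 0.15 (SD, n = 7 mice) in TR, 0.34 ± 0.27 (n = 21) in TRPhet and 0.09 ± 0.10 (n = 7) in TRPnull. TRPnull lay below TR (difference -0.36, exact permutation p = 0.000583, adjusted 0.00175) and below TRPhet (difference -0.25, exact permutation test, adjusted p = 0.0319). TRPhet and TR differed by -0.10 (exact permutation p = 0.354). These tests of the chromosome 6 level were not in the plan. The 1 TRPnull tumour with the gain was the array labelled TRPnull tumour 4, which matched the array labelled TRPhet tumour 4 within measurement noise. Without both arrays the genotype difference of the gain had an adjusted exact p of 0.00105.

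Within scan batches the difference between TRPnull and TR kept its sign. With tumours as units, the differences over all tumours were -8.66 for the altered share and -0.39 for chromosome 6. With labels permuted within batches, the altered share had a permutation p of 0.0280 (adjusted 0.0841) and chromosome 6 an adjusted permutation p of 0.0135. The permutations within batches or regions count the 2 tumours of 1 mouse as separate units. The differences of the altered share were -2.83 in batch 1, -6.10 in batch 2 and -22.1 in batch 8, and those of chromosome 6 were -0.21, -0.47 and -0.19. Batch 1 held 1 TR and 2 TRPnull tumours, and batch 2 held 4 and 3. Batch 8 held 1 of each, so its value rests on TR tumour 8, with an altered share of 22.1%, against a single tumour. Permuted within brain region, the altered share had an adjusted permutation p of 0.133 and chromosome 6 of 0.0169. Genotype and region were unbalanced: 5 of 8 TR tumours were BS, but 1 of 8 TRPnull tumours, TRPnull tumour 4. In BS chromosome 6 averaged 0.51 in TR (n = 5 tumours) and 0.28 in TRPnull (n = 1). In Ctx it averaged 0.28 (n = 1) and -0.01 (n = 2), and in Di 0.48 (n = 2) and 0.11 (n = 3). No TR tumour was OFB, so few tumours carry the comparison within regions. For TRPnull against TRPhet, chromosome 6 had an adjusted permutation p of 0.0590 within scan batches. TRPhet minus TR was -2.04, -4.54, 0.167 and 2.66 percentage points in batches 1, 2, 3 and 7, and TRPnull minus TRPhet was -0.795, -1.57, -1.20 and -3.06 in batches 1, 2, 4 and 6. For chromosome 6 the same batches gave -0.12, -0.26, -0.01 and 0.34 for TRPhet minus TR and -0.09, -0.21, -0.05 and -0.28 for TRPnull minus TRPhet. Batch 5 held TRPhet tumours only.

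The sex of the mice is not in the labels, but 7 of 8 TR tumours, 14 of 25 TRPhet tumours and 4 of 8 TRPnull tumours had X above and Y below the reference. Among these alone, TRPnull minus TR was -10.5 percentage points (n = 6 and 3 mice, exact permutation p = 0.0238, adjusted 0.0714) for the altered share and -0.38 for chromosome 6 (exact permutation p = 0.0119, adjusted 0.0357). At a size threshold of 0.5 the altered share differed by -1.94 (adjusted permutation p = 0.159), and the chromosome 6 gain by genotype had an adjusted exact p of 0.30. With each probe's median subtracted, a step that removes changes present in most arrays, that gain had an adjusted exact p of 0.351.

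**Figure D2:**
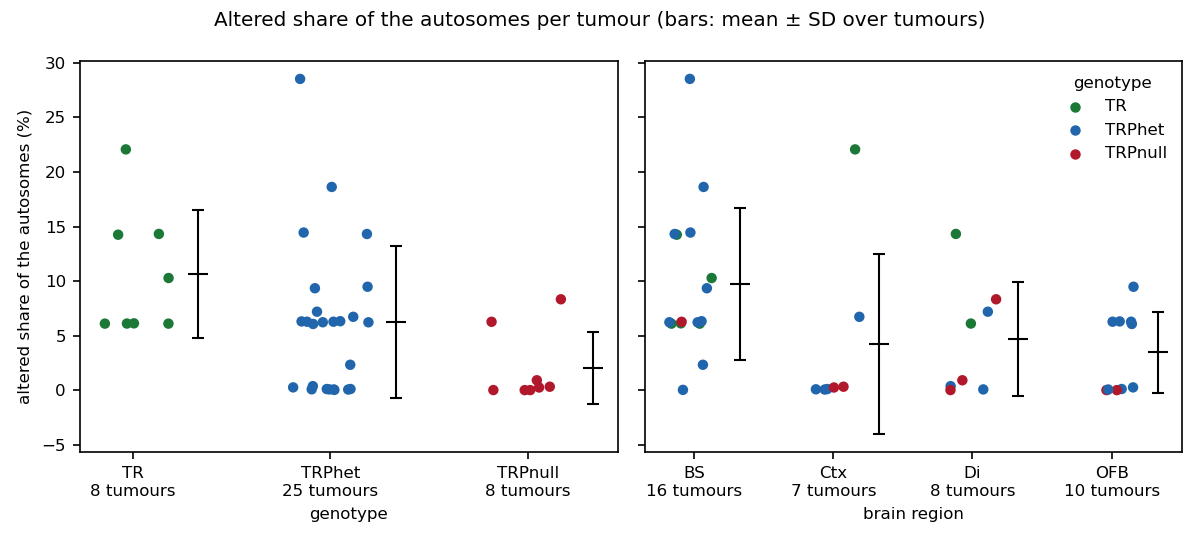
Altered share of the autosomes in percent (vertical axis) per tumour, by genotype on the left and by brain region on the right, with mean ± SD over tumours beside the points. Means over mice fell from 11.3% in TR to 2.28% in TRPnull.

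**Figure D3:**
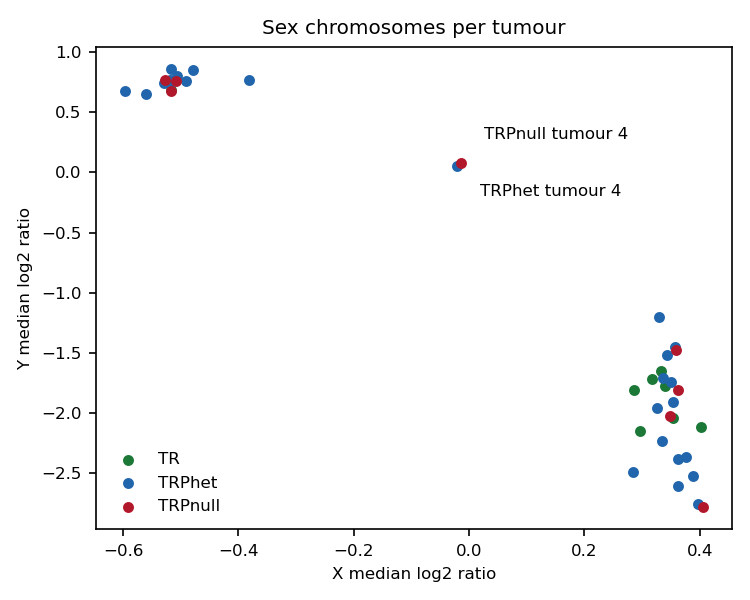
Median log2 ratio of the Y chromosome (vertical axis) against that of the X chromosome (horizontal axis) for each tumour, coloured by genotype. Of the 41 tumours, 25 lie at X values of 0.28 to 0.41, 14 at -0.60 to -0.38, and TRPhet tumour 4 and TRPnull tumour 4 between them.

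Gene by gene, the genotype differences did not pass adjustment over the genome. For TRPnull against TR, limma called 0 of 16308 genes (1501 at an unadjusted p under 0.05, smallest adjusted p = 0.101), and 128 of 2408 windows of 1 Mb, all on chromosome 6 and all lower in TRPnull (smallest adjusted p = 0.0469). Ezh2 differed by -0.49 ± 0.13 (SE), Met by -0.42 ± 0.12 and Klra2, a natural killer cell receptor gene, by -0.40 ± 0.11 (limma adjusted p = 0.101 for each). Adjusted over the list alone, 3 of 12 RAS and MAPK genes, 1 of 18 receptor tyrosine kinases (Met), 1 of 19 glioma suppressor and chromatin genes (Ezh2) and 2 of 14 entries of strain-variable segments (Klra2 and Ide) passed, and 0 passed in the PI3K, RB, p53, MYC and neural lists, where 0 passed over all genes too. Among the RAS and MAPK genes Braf differed by -0.37. Ide, the insulin-degrading enzyme gene on chromosome 19, differed by -0.55 ± 0.16.

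For TRPhet against TR, limma called 0 genes (1532 at an unadjusted p under 0.05) and 0 windows. The listed genes with the smallest p were Ppm1d, a phosphatase gene of the p53 pathway (0.13 ± 0.05, adjusted p = 0.424), Msh6, a mismatch repair gene (0.18 ± 0.07, adjusted p = 0.436), and Lzts1 (-0.22 ± 0.08, adjusted p = 0.452). For TRPnull against TRPhet, limma called 0 genes (1071 at an unadjusted p under 0.05) and 0 windows, with Met at -0.31 ± 0.10 and Klra2 at -0.26 ± 0.09 (adjusted p = 0.371 for both) and the PI3K subunit gene Pik3cd at 0.15 ± 0.06 (adjusted p = 0.411). Adjusted over the list alone, no list gave a call in either comparison.

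Tumours of the BS region carried the highest level of chromosome 6. Its mean log2 ratio was 0.48 ± 0.24 (SD, n = 16 tumours) in BS, 0.12 ± 0.18 (n = 7) in Ctx, 0.23 ± 0.20 (n = 8) in Di and 0.24 ± 0.22 (n = 10) in OFB. Region accounted for 31.6% of the variance (permutation p = 0.00292), in a test that was not in the plan. BS exceeded Ctx by 0.36 (adjusted exact permutation p = 0.0136), Di by 0.25 (adjusted exact permutation p = 0.0419) and OFB by 0.24 (adjusted permutation p = 0.0419). The whole chromosome gain was called in 14 of 16 BS, 2 of 7 Ctx, 3 of 8 Di and 5 of 10 OFB tumours. Chromosome 1 was gained in 5 BS and 2 Di tumours and in none of the Ctx or OFB tumours. The permutation p of the chromosome 6 effect was 0.00528 within scan batches, where BS exceeded the other regions by 0.23, 0.21, 0.12, 0.43 and 0.34 in batches 1, 2, 4, 5 and 7, and 0.00338 within genotypes. In batch 7 all 4 BS tumours are TRPhet and the other is TR, so region and genotype cannot be told apart there.

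**Figure D4:**
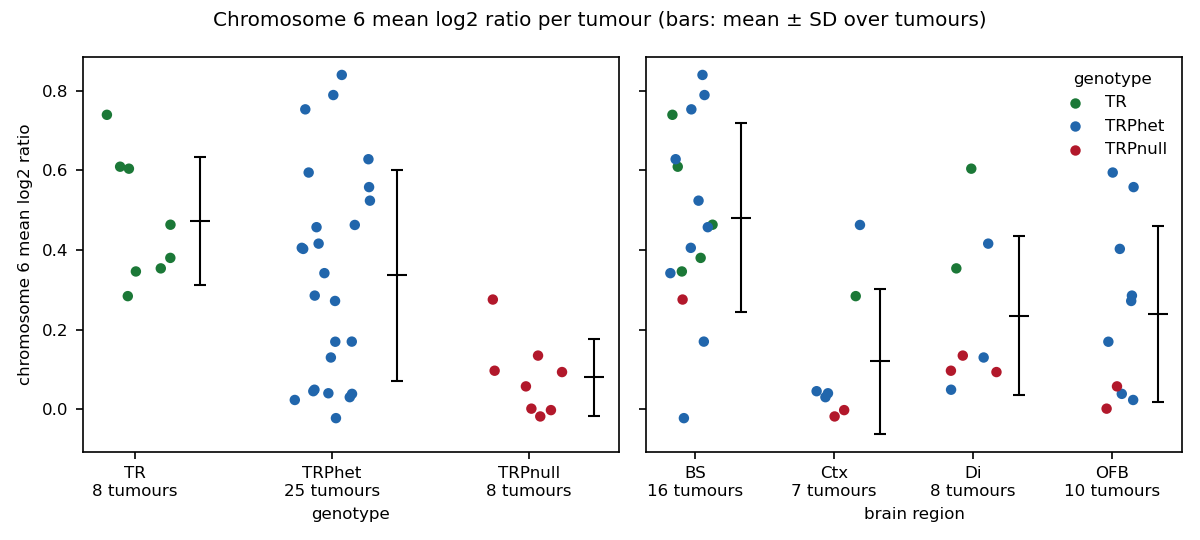
Mean log2 ratio of chromosome 6 (vertical axis) per tumour, by genotype on the left and by brain region on the right, with mean ± SD over tumours beside the points. BS tumours average 0.48 and Ctx tumours 0.12.

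The altered share averaged 9.72% ± 6.99 (n = 16) in BS, 4.22% ± 8.24 (n = 7) in Ctx, 4.66% ± 5.22 (n = 8) in Di and 3.48% ± 3.71 (n = 10) in OFB. The region effect on the altered share did not pass the threshold (17.9% of the variance, permutation p = 0.0567). Within scan batches BS exceeded the other regions by 4.76, 2.72, 2.29, 8.20 and 2.66 percentage points in batches 1, 2, 4, 5 and 7, with the same limit for batch 7. The gained share differed by region (22.8%, permutation p = 0.0194), with means of 9.30% in BS and from 2.60% to 4.42% in the other regions, but no pair of regions passed adjustment (smallest adjusted permutation p = 0.0829). Without TR tumour 8 the Ctx mean was 1.25% (n = 6) for the altered and 1.05% for the gained share, and the region effect on the altered share was 28.6% (permutation p = 0.00648). It also passed without TRPhet tumour 1 (21.8%, permutation p = 0.0262), TRPhet tumour 13 (20.5%, p = 0.0368), TRPhet tumour 22 (19.7%, p = 0.0427) or TR tumour 7 (21%, p = 0.0323).

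Among the 4 regions limma's F test called 275 of 16308 genes (1687 at an unadjusted p under 0.05), 272 on chromosome 6 and 3 on chromosome 1. Foxm1 averaged 0.70 ± 0.23 (SD) in BS, 0.27 ± 0.25 in Ctx, 0.39 ± 0.25 in Di and 0.36 ± 0.28 in OFB (adjusted p = 0.0416). Klra2 averaged 0.49, 0.13, 0.24 and 0.20 in the same order (adjusted p = 0.0452). Gpnmb, a melanosome and glioma-associated glycoprotein gene, had the smallest p, with means of 0.55, 0.30, 0.27 and 0.27 (adjusted p = 0.0250), and was chosen after its values were seen. Adjusted over the list alone, 2 RAS and MAPK genes, 2 RB and cell cycle genes (Ccnd2 and Ccne1), Foxm1 and Klra2 passed, against 1, 0, 1 and 1 over all genes, and no gene of the receptor tyrosine kinase, PI3K, p53, glioma suppressor or neural lists did. The count of genes was 0 with scan batch as a covariate (1138 at an unadjusted p under 0.05), 0 with genotype, region and diagnosis in one model (1573) and 0 with centring on the densest value (1385), so these calls end under each of these settings.

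Tumours labelled GBM and A3 did not differ in copy number change. The altered share averaged 6.79% ± 7.53 (SD, n = 23 mice) in GBM and 6.20% ± 5.89 (n = 11) in A3, a difference of 0.588 percentage points (permutation p = 0.825). The gained share differed by -0.121 (permutation p = 0.961) and the lost share by 0.709 (permutation p = 0.265). Without TR tumour 8 the lost share differed by 0.283 (permutation p = 0.132) and the altered share by -0.107 (permutation p = 0.969). Large segments were called in 19 of 28 GBM and 7 of 12 A3 tumours. The 1 GC-GBM tumour, TRPhet tumour 7, carried the gain of chromosome 6 (mean 0.46). Partial losses of chromosomes 1, 8, 14 and 15 were called in it with means of -0.26, -0.21, -0.22 and -0.21, near the threshold of 0.2. Limma called 0 of 16308 genes between GBM and A3 (62 at an unadjusted p under 0.05) and 0 windows. The listed genes with the smallest p were Cyp2d22 (0.07 ± 0.05), the neural progenitor filament gene Nes (0.07 ± 0.05) and the growth factor receptor gene Fgfr1 (0.04 ± 0.03), each at an adjusted p of 1, and no list gave a call adjusted over the list alone.

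In 6 mice, 2 tumours from different brain regions were measured. TR tumours 3 and 6 shared all their altered windows of large segments (Jaccard index 1), TRPhet tumours 6 and 11 had an index of 0.948, TRPhet tumours 9 and 17 of 0.434, and in the other 3 mice it was 0, because none of their tumours had a large segment to share, so these pairs are empty and not unlike. Wherever the index was above 0, the shared windows lay on chromosome 6. Its gain was called in 24 of 41 tumours and in all 8 TR tumours, so tumours of different mice share it too. The mean index of 0.397 compared with 0.20 over all 720 matchings (one-sided exact permutation p = 0.05), which did not pass the threshold of 0.05. With the Pearson correlation of segment means the mean was 0.730 against 0.504 (one-sided exact permutation p = 0.0347). Among the 4 TRPhet mice alone, where genotype cannot bring likeness, the index was 0.346 against 0.175 over 24 matchings (one-sided exact permutation p = 0.167). TRPhet tumours 12 and 20, and 18 and 19, had no large segment, so exchanging partners among these pairs leaves the mean unchanged. With so few matchings p could not fall under 0.05, and the test decides nothing.

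Narrow segments, under 5 Mb, recurred in the same direction in at least 4 mice at 13 regions. A gain on chromosome 17 (30176354 to 30650272), over the glyoxalase gene Glo1, Btbd9 and the dynein gene Dnahc8, was present in 15 mice with a mean of 0.52. A loss on chromosome 19 (37295134 to 37436176), over Ide, was present in 8 mice (mean -0.44). A gain on chromosome 2 (77680396 to 77822062) was present in 12 mice (mean 2.55), and a loss on chromosome 4 (111622322 to 112657165) in 7 mice (mean -2.14). That interval overlaps genes of the Skint family: Skint2 and Skint3 were called lost in 8 tumours and gained in 8, with single segments down to -4.09 and up to 1.12. The loss from 112926405 to 113386081 (7 mice, -0.95) and the gain from 111579573 to 113200796 (7 mice, 0.63) lie beside it or over it, and a loss lies farther along chromosome 4 (144867593 to 146628957, 6 mice, -0.48). Chromosome 1 had a loss from 173351486 to 173405431 over Itlna and Cd244 (5 mice, -1.13), chromosome 7 a gain from 15053024 to 15063148 (5 mice, 0.50) and chromosome 17 a gain from 6180566 to 6408985 (4 mice, 0.48). Against the reference, 4 listed entries of strain-variable segments rose with treat (Klra2, Glo1 and Dnahc8, also listed as Dnah8) and 2 fell, Ide (-0.28, adjusted p = 0.0129) and Nnt, a mitochondrial transhydrogenase gene (-0.19, adjusted p = 1.54e-05), of 14 tested, and 6 passed adjusted over the list alone. The natural killer receptor gene Klra1 lies on chromosome 6 and was called gained in 18 tumours and lost in 1, most tumours having gained the whole chromosome, and did not pass treat (0.07, adjusted p = 1). Entpd4 was called lost in 3 tumours.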

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

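The 3 tests of the likeness of a pair of arrays were chosen after the likeness was seen, and so was the run without TR tumour 8. The arrays labelled TRPhet tumour 4 and TRPnull tumour 4 correlated at 0.977 over all autosomal positions, against 0.914 for the next closest pair of the 820. The SD of their difference was 0.805 of the SD from duplicate spots, against 1.92 for the pair with the next highest correlation and above 1 for every other pair, so the same DNA on both arrays may account for the likeness. Both had X medians near 0 (-0.02 and -0.01) and Y medians near 0 (0.0512 in TRPhet tumour 4 and 0.0749 in TRPnull tumour 4), a signal of Y that lies outside every total, while the other tumours had Y medians of -2.79 to -1.20 or of 0.66 to 0.86. Reference DNA in the tumour channel is argued against by the gain of chromosome 6 on both arrays, with 0.27 as the lower mean, whereas a mix of DNA of both sexes stays open, with 0.0749 as the higher Y median. Which genotype label belongs to the DNA is not given in the sources used here, and no biological explanation was tested.

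Single tumours lay far from the others of their group in 6 of 30 groups and measures tested. For normally distributed values chance gives about 1 in 20, but the lost share is skewed and bounded at 0, and TR tumour 8 accounts for 3 of the 6, so this rate need not apply. TR tumour 8 had a lost share of 10.2%, against 0.121% for the nearest TR tumour and 0.570% for the nearest Ctx tumour. Among Ctx tumours it also had the highest altered share (22.1%, nearest 6.72%). The losses of chromosomes 7 and 11 make up most of its lost share. TRPhet tumour 22 stood apart among OFB tumours in its lost share (2.19%, nearest 0.226%), most of which is its loss of chromosome 19. TRPnull tumour 3 had a chromosome 1 mean of 0.23, with 0.08 as the nearest TRPnull tumour, and TRPhet tumour 5 a lost share of 1.07%, with 0.336% as the nearest Di tumour.

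Whether BS differs from the other regions alike in TRPhet and TR stays open. In TRPhet the altered share averaged 10.6% in BS and 3.29% elsewhere, and in TR 8.57% in BS and 14.2% elsewhere, a difference of differences of 12.9 percentage points (unadjusted permutation p = 0.0159, the only one of 4 interactions tested with a p under 0.05). Without TR tumour 8 it was 8.99 (permutation p = 0.0767), so the low p rests on that tumour. For chromosome 6 the same interaction was 0.16 (permutation p = 0.398).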

How the results depend on the processing

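The runs without TRPhet tumour 22, without both alike arrays and with only the tumours whose X lay above and Y below the reference were chosen after the data were examined. Over all alternatives, the main results reported here kept direction and side of the threshold in 339 cases, passed it newly in 18, no longer passed it in 5, moved in 23 and reversed in 12. For single genes and chromosomes the numbers were 364 kept, 32 no longer past the threshold, 4 moved and 1 reversed. The cause was not tested unless stated.

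The altered share of TRPnull minus TR no longer passed at a size threshold of 0.5 (-1.94, adjusted permutation p = 0.159), with probe medians subtracted (-3.48, p = 0.436, a step that removes changes present in most arrays), with labels permuted within brain region (-8.66, p = 0.133) or scan batch (-8.66, p = 0.0841), and in the tumours chosen by X and Y (-10.5, p = 0.0714, fewer mice). The -8.66 is the difference over all tumours, and only the permutations were kept within region or batch. Over the other alternatives TRPnull minus TR stayed negative and passed, down to -16.2 with centring on the densest value (adjusted permutation p = 0.00524). TRPhet minus TR reversed at 0.5 (0.0826) and in BS tumours only (2.07), and passed with normexp (-7.15, adjusted permutation p = 0.0357). TRPnull minus TRPhet passed at 0.3 (-4.61, adjusted permutation p = 0.0389). The region effect passed at thresholds of 0.15 (20.1%) and 0.3 (19.4%), penalty factor 2 (18.9%), normexp (23.5%), without noisy arrays (27.1%) and without TRPhet tumour 22 (19.7%), with permutation p from 0.0170 to 0.0476. GBM minus A3 reversed at 0.3 (-0.0889) and 0.5 (-0.147), with centring on the densest value (-2.13) and with normexp (-0.0454).

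Tumours with a large segment numbered 13 at 0.5 and 34 from 1 Mb, where inherited variants may be counted too. Recurrent chromosomes fell from 2 to 1 at 0.3, at 0.5 and with centring on the densest value, and rose to 3 with probe medians subtracted. Chromosome events that differ by genotype fell from 1 to 0 at 0.5 and with probe medians subtracted. The likeness of tumours of 1 mouse passed at 0.3 (0.421), penalty factor 2 (0.386), with probe medians subtracted (0.553) and by Pearson correlation (0.730), with exact permutation p from 0.0333 to 0.0417. Over its other alternatives it did not pass, with p up to 0.283 at 0.15, and among the TRPhet mice alone it could not.

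With limma, genes that differ by region numbered 0 with centring on the densest value, in the joint model and with scan batch (1385, 1573 and 1138 at an unadjusted p under 0.05), 745 with normexp, 731 without noisy arrays, 148 with at least 5 probes and 78 as windows. For TRPnull against TR 128 windows passed. Against the reference, treat called 6074 at a bound of 0.05, 533 at 0.2, 1368 without noisy arrays, 5944 with at least 1 probe, 787 with at least 5, 153 windows, 57 in the joint model and 0 with probe medians subtracted (7 at an unadjusted p under 0.05), where Klra2 reversed (-0.00559).

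Leaving out each mouse in turn gave 14.8% to 28.6% for the region effect, -0.400 to 1.41 for GBM minus A3, -5.81 to -2.92 for TRPhet minus TR, -10.1 to -7.25 for TRPnull minus TR (adjusted permutation p from 0.0157 to 0.0350) and -5.33 to -3.23 for TRPnull minus TRPhet. TRPhet minus TR passed without TRPhet tumour 24 (-5.81, adjusted permutation p = 0.0315). The region effect passed without TR tumour 8 (28.6%), TRPhet tumour 1 (21.8%), TR tumour 7 (21%), TRPhet tumour 13 (20.5%) or TRPhet tumour 22 (19.7%).

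A GC correction was not run, since no mm8 genome was used here. Averaging mice without a block could not be applied to the region comparison, where the tumours of 1 mouse lie in different regions. Signal limits the short segments: on a noisy array 2 of 19 inserted segments of 100 probes with a shift of 0.3 were found, against 19 of 19 on a quiet one.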

Other observations

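The tests of random places for the narrow segments, of chromosome 1 beside chromosome 6 and of the height of the chromosome 6 gain were chosen after the values were seen. The higher level of chromosome 6 in BS tumours was set against 3 technical or design explanations. Within scan batches the region effect had a permutation p of 0.00528, within genotypes of 0.00338, and after a linear term for the array noise of 0.00405, which argues against each of these as the whole cause. With the batch means removed, region still accounted for 28% of the variance. A biological difference between tumours of the brain regions stays open as a hypothesis, since it was found and tested on the same data.

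The narrow segments that recur over mice may be inherited variants of the mouse strains and not events of the tumours. Their calls matched in 87.2% of comparisons between the tumours of 1 mouse, against 71.8% on average over all 720 matchings (one-sided exact permutation p = 0.00556). A region called in neither tumour counts as a match. TR tumours 3 and 6, on noisy arrays with 0 and 1 narrow segments, matched in 100%. So did TRPhet tumours 18 and 19, on quiet arrays with 7 and 6. Like noise within a mouse can thus raise the agreement, and the test does not separate it from inheritance. Noise of single arrays is argued against as the source of the recurrence: with the narrow segments of each mouse moved together to random places of the autosomes, 2 of 10000 placements gave any region in at least 4 mice and none gave more than 1, against the 13 found (one-sided permutation p = 0.000100, the smallest that 10000 placements can give). The first test chosen for noise, the number of these regions per tumour against the array noise (Spearman rho -0.604), decides nothing, since the penalty of the segmentation grows with the noise and lowers the calls. Probes that err alike on several arrays were not tested and stay open. Normal tissue of the same mice was not analysed here, so events shared by the tumours of a mouse stay open too.

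Gain of chromosome 1 was present beside gain of chromosome 6 in 6 mice, where independence gives 4.2. The test does not tell whether the gains go together (Fisher exact p = 0.203), with 1 mouse gaining chromosome 1 alone, 15 chromosome 6 alone and 13 neither.

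In 8 tumours of 7 mice the mean of chromosome 6 lay above 0.58, the log2 ratio of 3 copies over 2, and the highest value was 0.84. More than 1 extra copy of chromosome 6 in part of the cells may account for these 8 tumours. The highest level of a whole gain of another chromosome was 0.44, and with centring on the densest value 10 tumours lay above 0.58.

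Of 100 splits of the tumours into 4 sets of the region sizes, the real one included, 2 gave at least as many genes as the real 275, with 299 as the highest other, a share under 0.05. Since 272 of these genes lie on chromosome 6 and move together, and another split gave more, the splits do not exclude chance. The splits treat the tumours of 1 mouse as independent, and the count was 0 with scan batch as a covariate. For the 3 genotype comparisons and for GBM against A3, limma called 0 genes in the real split. All 100 splits then give as many whatever the data, which tells nothing about chance. The highest other counts were 539 for TRPhet against TR, 1 for TRPnull against TR, 750 for TRPnull against TRPhet and 1316 for GBM against A3 (unadjusted p under 0.05 in the real splits: 1532, 1501, 1071 and 62 genes). Any gene was called in 7, 1, 6 and 5 of the other splits in the same order. So few splits with calls are near what an adjusted threshold of 0.05 gives by chance, and the high counts in them point to values shared by many genes or to a structure of the samples, which was not tested.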
